A study of Triticum aestivum with 6 samples.

How the data were processed

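Messenger RNA was profiled by sequencing in leaf tissue of winter wheat seedlings (Triticum aestivum, breeding line SE15) collected 7 days after germination. Per the labels, 3 samples came from seeds sonicated before germination and 3 from untreated seeds. The treatment was 30 kHz and 70 W for 5 minutes at 4 cm from the ultrasound head, and each group started from 100 seeds with a water content of 13.6% that germinated at 20 °C in the dark. The extraction text in the labels names a kit for genomic DNA and then mRNA purified from total RNA, and no RNA kit is named there. Per the labels' protocols, mRNA was enriched with poly-T beads, converted to cDNA from random hexamers and sequenced on an Illumina NovaSeq instrument. The protocol text describes no strand marking. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, STAR 2.7.10a and DESeq2 without a version, and they give neither the role nor the order of the tools. The genome build and annotation are not given in the sources used here.

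The data analysed here were 2 tables of the authors' own comparison between groups that the headers call K1 and US1. Both hold statistics per transcript-model probe, with the chromosome, start, end and strand of the probe and the description of an overlapping gene. Neither holds values per library, so depth, replicate spread and expression level are unknown, and no test of expression could be run. The planned edgeR or limma test needs values per library and was not run. Per the file headers, the first table gives the authors' DESeq2 p-value, adjusted p-value (FDR), log2 fold change and shrunk log2 fold change for 861 probes. The second table, per the file headers from a selection called ID, gives a deposited p-value, an FDR and a score, the Z-score of the difference, for 52 probes. The test behind that score is not given in the sources used here. Its p-values matched the one-sided normal tail of the score's absolute size, such as 1.44e-06 at a score of -4.68. The first table's p-values were taken as two-sided, so the FDR thresholds of the 2 tables are not alike. Every listed probe had an FDR under 0.05 in its table, so genes outside the selection could not be compared.

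The headers do not say which group is the numerator, nor which of the 3 libraries per group entered. The sign was therefore kept as deposited, and genes are described as lying on the positive or the negative side of the authors' log2 fold change. If US1 was divided by K1, positive values would mean higher expression after ultrasound, but no header states this.

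From the deposited values 3 quantities were derived. An implied standard error was taken as the absolute log2 fold change divided by the normal quantile of the two-sided p-value, which assumes a Wald test. As a check on that assumption, the ratio of unshrunk to shrunk fold, minus 1, was divided by the squared implied standard error. A normal shrinkage prior makes this quotient nearly constant, and its median was 1.83 with quartiles of 1.82 and 1.85. The number of tests behind each FDR was recovered from FDR times rank over p, which gave 76618 for the first table and 120099 for the second. The FDR of the last probe in the first table implied rank 867, so 6 further probes may have passed the threshold without being analysed here. Each probe was identified by the wheat gene in its name. For 24 probes the annotated feature was another gene on the opposite strand, and the description was then not used. This left 232 probes with a description of their own gene, while 620 probes had no description. The RefSeq gene table matched 0 of the 861 gene identifiers and was not used further. Positions are as deposited and were not converted.

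Every sample was placed in its group by its title in the labels. Before the data were examined, 21 gene lists were fixed as keyword patterns over the descriptions, together with the rule for named genes. Per direction, the rule takes the 12 described genes with the largest absolute log2 fold change. It adds the 3 largest of each list with at least 5 members and up to 15 of the genes shared by both tables, again by size, which gave 53 genes. Non-overlap of the replicate ranges, which the rule also asks for, could not be checked. For each of the 11 lists with at least 5 members, the share of members on the positive side was compared with that of all other listed genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. Subgenome and direction were compared by a permutation test on the chi-square statistic with 100000 shuffles. A count adjusted over the list alone was not computed, because p-values of members outside the tables are not analysed here. Genes are not independent replicates, so these tests describe the listed genes and not the seedlings. The alternatives tried were a stricter FDR, a minimum fold, other background genes, one vote per description and one probe per overlapping group.

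The list test, the recovery of the number of tests, the implied standard error, Cochran's Q, the random placement of genes and the subgenome test were tested on simulated data. With directions shuffled over the 861 genes, 0.18% of lists were called, and a first list planted at 95% positive was called in 100% of runs. These shuffles treated genes as independent and do not cover genes of the same description that share a direction. Where such genes fill a list, its Fisher p-value may be too small. Cochran's Q called 4.3% of simulated sets of equal folds with independent errors different, and the subgenome test called 4.0% of shuffled sets. The sets for Cochran's Q used the standard errors of the 37 chlorophyll a-b binding genes, without selection by p-value. They do not cover folds selected as the listed ones were, nor other sets of genes. The number of tests was recovered within 1 in 90% of runs of 76618 simulated p-values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.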

Results

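Leaf transcriptomes of week-old wheat seedlings were profiled in 3 samples grown from ultrasound-treated seeds and 3 samples grown from untreated seeds. Which of these samples entered the authors' comparison is not stated. The values below are the authors' own statistics for this one comparison, with an FDR under 0.05 for every listed gene. No depth or value per library is known, and n could be no more than 3 per group. Nothing in the labels says whether the samples of a group came from separate dishes, so the authors' p-values may measure technical spread only. The genome build behind the positions is not given in the sources used here, and every probe was annotated as a gene, with no exon or UTR given. Folds are given on the authors' log2 scale with the implied standard error (SE). The orientation of the sign is not stated, so genes are placed on a positive and a negative side. The positive side would be higher expression after ultrasound if the second-named group, US1, was divided by the first-named, K1.

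The comparison asks which transcripts differ in the week-old seedling when its seed was sonicated before germination. The authors' deposited DESeq2 table listed 861 genes, 1.12% of the 76618 tests implied by the FDR values. Of these, 441 lay on the positive and 420 on the negative side. The positive side held nearly all listed genes of light harvesting and carbon fixation, and all listed histone genes. The negative side held alcohol dehydrogenases, most of the kinase and signalling list and a set of E3 ubiquitin ligases. The median log2 fold change was 1.90 on the positive side (3.72-fold) and -1.71 on the negative side (3.26-fold). The smallest absolute change listed was 0.83, and effects of genes outside the table are not analysed here. The median implied SE was 0.43, with a range from 0.22 to 2.13. At an FDR under 0.01 the counts dropped to 169 positive and 192 negative genes.

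Photosynthesis genes formed the largest described group. Of 60 listed members, 59 lay on the positive side, against 47.7% of all other listed genes (Fisher's exact test, adjusted p = 3.47e-16 over 11 lists). The list was chosen before the data were examined, but its members were selected by the authors on these samples, so the count is not independent evidence of direction. Descriptions were also unevenly spread, with 70.3% of described genes on the positive side, against 44.2% of those without a description of their own (9 of which carried that of another gene). Against the 172 other described genes, a background chosen after the data were seen and of which 60.5% were positive, the exact test gave an adjusted p of 6.66e-09. With one vote per description, also chosen afterwards, all 10 photosynthesis descriptions were positive, ferredoxin by 2 genes to 1, and the adjusted exact p was 0.0421. These votes included ferredoxin-nitrite reductase, an enzyme of nitrogen assimilation, and a further description of ferredoxin. The test was not repeated without them.

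All 37 listed genes of the chlorophyll a-b binding proteins, which hold the antenna pigments of the photosystems, were positive. They lay on 18 chromosomes, with 11 on subgenome A, 12 on B and 14 on D. Their median log2 fold change was 2.63 (6.19-fold), and the median of the authors' shrunk values was 1.72. The authors' FDR was under 0.01 for 35 of them. TraesCS5A02G454200 (chromosome 5A, 635407574 to 635408909, minus strand) had the lowest FDR of the table. Its log2 fold change was 6.18 (SE 0.54, shrunk 3.97), an unshrunk ratio of 72.7, with a DESeq2 adjusted p of 5.02e-25. Its neighbour TraesCS5A02G454300 (635410444 to 635411662) had a log2 fold change of 5.11 (SE 0.49, DESeq2 adjusted p = 2.92e-21). Another member, TraesCS5D02G464900 on 5D, had a larger fold of 7.01, but it was less precise (SE 1.58), and its shrunk value was 1.18. TraesCS1B02G433300 (5.79, SE 0.94), TraesCS1B02G317500 (4.77, SE 0.71), TraesCS1D02G375100 (4.45, SE 0.77) and TraesCS5D02G464700 (4.01, SE 0.52) were named because both of the authors' tables held them, and others not named here had folds of similar size. TraesCS6A02G093700 (3.79, SE 0.55) and its counterpart in description on 6D, TraesCS6D02G088800 (3.44, SE 0.53), were also positive. The 9 listed genes of the small chain of ribulose bisphosphate carboxylase, the enzyme that fixes carbon dioxide, were all positive, with a median log2 fold change of 1.79 and a range from 1.56 to 2.77. Plastocyanin, photosystem I and photosystem II genes in the list were positive as well. The single negative member was a ferredoxin, TraesCS3D02G366600, at -2.56 (SE 0.46), named after its value was seen. The keyword list also took in 3 ferredoxin-nitrite reductases, which assimilate nitrogen. The one with the largest fold, TraesCS6B02G364600, had a log2 fold change of 6.29 with an SE of 1.77 and a DESeq2 adjusted p of 0.0401.

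**Figure D1:**
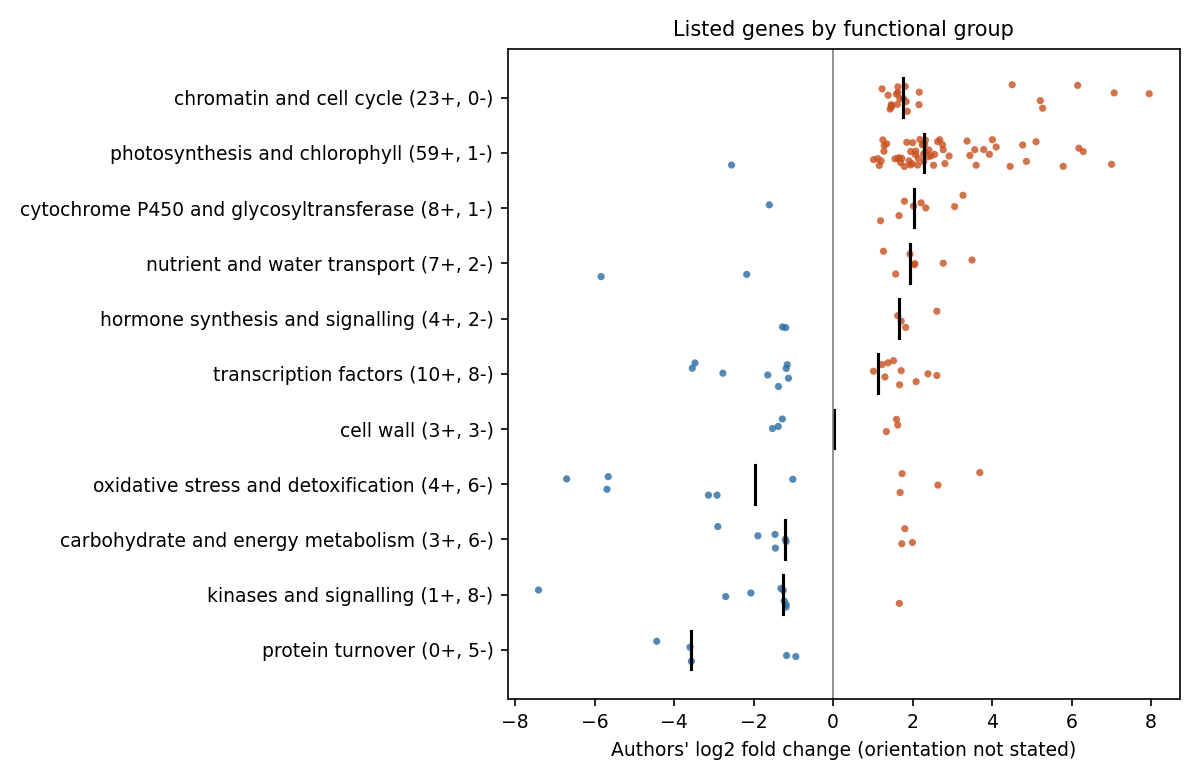
Authors' log2 fold change (horizontal axis, orientation not stated) of listed genes in the 11 functional lists with at least 5 members. Each point is a gene, coloured by side, the black line is the list's median and the label gives the numbers of positive and negative members, with 59 of 60 photosynthesis genes and all 23 chromatin genes to the right of 0.

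The chromatin and cell cycle list held 23 genes, all on the positive side (Fisher's exact test, adjusted p = 1.13e-06). Its members were 19 histone genes, whose proteins package DNA, 3 genes described only by a histone-fold domain and 1 tubulin beta chain gene. The histones had a median log2 fold change of 1.63 (3.09-fold, range 1.23 to 7.95), and only 2 of the 19 had an FDR under 0.01. The largest folds were imprecise, with histone H2B TraesCS5A02G384300 (5A, 582106947 to 582107732) at 7.95 (SE 1.63, shrunk 1.15) and histone H4 variant TraesCS2D02G391500 at 7.07 (SE 1.66, shrunk 1.02). Histone H3.2 TraesCSU02G095800, on unplaced sequence, had 5.21 (SE 1.40). The histone-fold genes, which need not be histones because the domain occurs in other proteins too, lay on 4A, 4B and 4D and all had an FDR under 0.01. The first and last of these, TraesCS4A02G081000 and TraesCS4D02G223400, had log2 fold changes of 5.27 (SE 0.81) and 6.15 (SE 1.14). With one vote per description, the 8 chromatin descriptions no longer passed against other described genes (exact test, adjusted p = 0.0611).

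Kinase and protein turnover genes lay mainly on the negative side, but neither list passed the planned test. Of 9 genes in the kinase and signalling list 8 were negative (exact test, adjusted p = 0.0669), and of 5 protein turnover genes 5 were negative (adjusted p = 0.0750, exact test). Against other described genes only, the background chosen after the data were seen, both passed, with adjusted exact p-values of 0.00114 and 0.00576. That background held the photosynthesis and chromatin lists, which were nearly all positive, so both passes rest partly on those lists. With one vote per description the kinases did not pass (adjusted exact p = 0.0611), and protein turnover, with 2 descriptions, was not tested. A mitogen-activated protein kinase gene, TraesCS7A02G422500, had the largest negative fold of a described gene, -7.42 (SE 1.62, shrunk -1.13). Serine/threonine kinase genes TraesCS4B02G120400 and TraesCS4A02G194800 had -2.71 (SE 0.72) and -2.07 (SE 0.42). The list also held a phosphofructokinase, an enzyme of glycolysis and not of signalling, and lipid kinases. Its only positive member, TraesCS1D02G244200 (1.66, SE 0.42), named after its value was seen, was described as a kinase regulator and not a kinase. The turnover genes were 3 RING-type E3 ubiquitin transferases, which mark proteins for degradation, and 2 SUMO ligases. The RING-type genes were one each on 6A, 6B and 6D. TraesCS6A02G382300 had a log2 fold change of -4.44 (SE 0.97), TraesCS6D02G367100 of -3.60 (SE 0.67) and TraesCS6B02G420600 of -3.57 (SE 0.80).

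Genes of carbohydrate and energy metabolism were split, with 3 positive and 6 negative members (exact test, adjusted p = 0.519). Against other described genes the adjusted exact p was 0.0483, and with one vote per description it was 0.0611. The other described genes again included the nearly all positive photosynthesis and chromatin lists, and a background without those lists was not tried. The alcohol dehydrogenases, which act in fermentation, were negative, with ADH2A (TraesCS4A02G202200) at -2.90 (SE 0.53, DESeq2 adjusted p = 5.40e-05) and ADH1A (TraesCS4A02G202100) at -1.89 (SE 0.39). The 3 positive members were fructose-bisphosphate aldolases, led by TraesCS5A02G108000 at 1.99 (SE 0.39). Oxidative stress genes numbered 4 positive and 6 negative (exact test, adjusted p = 0.739). Peroxidases, which oxidise substrates with hydrogen peroxide, lay on both sides, and TraesCS3D02G406900 (-6.71, SE 1.73), TraesCS1B02G355200 (-5.69, SE 1.63) and TraesCS1B02G355000 (-5.66, SE 1.56) led the negative side.

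Transcription factors divided into 10 positive and 8 negative genes (exact test, adjusted p = 0.895). WRKY factors TraesCS5A02G225600 and TraesCS1D02G300700 had log2 fold changes of -3.55 (SE 0.78) and -3.48 (SE 0.74), and MYB transcription factor 78 (TraesCS4A02G118400) had -2.77 (SE 0.43, DESeq2 adjusted p = 3.21e-07). Hormone genes had 4 positive and 2 negative members (adjusted exact p = 0.840). Ethylene-responsive factor 6 (TraesCS1B02G231500) was at 2.61 (SE 0.70), a brassinosteroid-related factor (TraesCS2A02G187800) at 1.71 (SE 0.49) and a lipoxygenase (TraesCS5B02G382300) at 1.82 (SE 0.41). The lipoxygenase overlaps an opposite-strand gene listed with the same fold of 1.82. Glycosyltransferases, which transfer sugars, were positive in 8 of 9 cases (adjusted exact p = 0.0849), with TraesCS4A02G481000 at 3.27 (SE 0.91), TraesCS7A02G558600 at 3.06 (SE 0.83) and TraesCS3D02G326200 at 2.33 (SE 0.67). The transport list had 7 positive and 2 negative members (adjusted exact p = 0.327). A peptide transporter (TraesCS3B02G454000) was at -5.84 (SE 1.56), nitrate reductase (TraesCS6A02G017500), matched by its keyword though it is an enzyme of nitrogen assimilation, at 3.49 (SE 0.86) and a metal-nicotianamine transporter (TraesCS6B02G283900) at 2.77 (SE 0.74). Cell wall genes were evenly divided, 3 and 3 (adjusted exact p = 1.00). They included a hydroxyproline-rich glycoprotein (TraesCS1D02G422700, 1.62, SE 0.38), a fasciclin-like protein (TraesCS1A02G396800, 1.59, SE 0.46) and a pectin acetylesterase (TraesCS3D02G538500, -1.53, SE 0.44).

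The other 10 lists had fewer than 5 members and were not tested. Heat shock genes numbered 1 positive and 1 negative, organelle genome keywords 1 and 1, defence genes 2 and 2, and metal binding genes 1 and 2. The organelle keywords matched a photosystem II repair protein and a gene similar to a heavy metal ATPase. Both lay on nuclear chromosomes, so neither was encoded in an organelle. Phenylpropanoid genes numbered 0 and 1, ribosome and translation genes 3 and 1, and lipid genes 1 and 3. The 3 positive members of the ribosome and translation list were glutamyl-tRNA reductases, enzymes of chlorophyll synthesis matched by the keyword for transfer RNA, so only the negative member, a translation initiation factor, belonged to translation. No gene of this table matched the keywords for seed reserves, which would mark endosperm or embryo tissue, for light signalling and the clock, or for transposable elements. With 72.0% of genes undescribed, these counts do not show absence.

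Among described genes outside the 11 tested lists, the largest negative folds were those of phenylalanine ammonia-lyase TraesCS1B02G048100 (-7.14, SE 1.64), the entry enzyme of phenylpropanoid synthesis, a very-long-chain hydroxyacyl-CoA dehydratase (TraesCS3B02G089500, -6.66, SE 1.63) and an MLO-like protein (TraesCS2B02G097800, -6.60, SE 1.74). On the positive side they were a purple acid phosphatase (TraesCS6B02G142700, 6.45, SE 1.75) and a 3-ketoacyl-CoA synthase (TraesCS7D02G089200, 5.67, SE 1.09), which elongates fatty acids. Size and precision were linked, largely by construction, because the SE was derived from fold and p-value and every listed p-value was small. All 52 genes with an SE above 1.3 had an absolute log2 fold change of at least 5.03, and none of them exceeded 1.67 after the authors' shrinkage. The 12 positive genes with the largest unshrunk folds shared 0 members with the 12 largest by shrunk fold, and the same held for the negative side. Of the 12 largest shrunk positive folds, 8 were chlorophyll a-b binding genes.

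**Figure D2:**
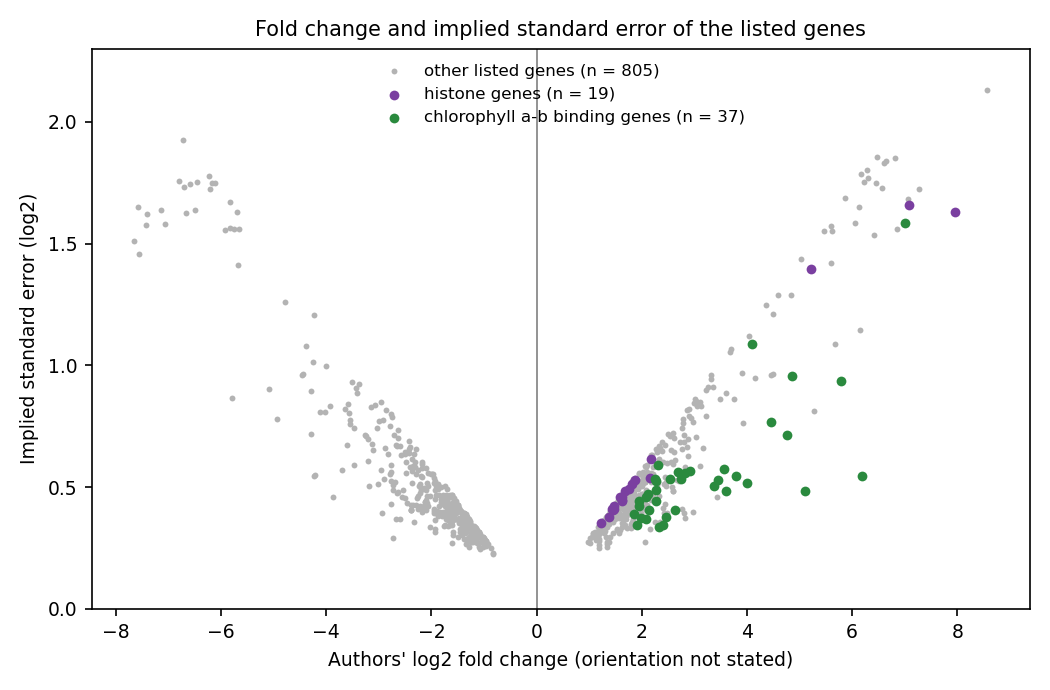
Authors' log2 fold change (horizontal axis, orientation not stated) against the implied standard error (vertical axis, log2 units) of the 861 listed genes, each a point. Most of the 19 histone genes lie along the upper edge of the right-hand cloud, where genes only just pass the threshold, and many of the 37 chlorophyll a-b binding genes lie below it, with smaller errors for their fold.

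The authors' second deposited table listed 52 genes, and it too was led by photosynthesis. It held 20 chlorophyll a-b binding genes and 6 genes of the small chain of ribulose bisphosphate carboxylase, all with a negative Z-score. In total 49 of its genes had a negative and 3 a positive Z-score. It shared 18 genes with the DESeq2 table, and all 18 had opposite signs in the 2 columns, so for these genes a negative Z-score went with the positive side of the log2 fold change. Of the shared genes 15 lay on the positive and 3 on the negative side, and 11 were chlorophyll a-b binding genes. The shared genes without a description were TraesCS7D02G057200 (8.57, SE 2.13, shrunk 0.50), TraesCS2B02G510200 (4.45, SE 0.96), TraesCS1D02G027300 (3.13, SE 0.83), TraesCS5D02G227500 (-4.23, SE 0.54), TraesCS5D02G227000 (-4.22, SE 0.55) and TraesCS6A02G350300 (-3.71, SE 0.57). The other 34 genes were in the second table only. They included all 6 small chain genes, none of which was in the DESeq2 table, and 9 of the 20 chlorophyll a-b binding genes. Among those 9 was the gene with the most extreme score, TraesCS5D02G329200 (Z-score -10.02), which was named after its value was seen. The 34 also held 3 peroxidases, 2 dirigent proteins, 2 lipoxygenases and 2 non-specific lipid-transfer proteins, all with negative scores. The lipid-transfer proteins were the only members of the seed reserve list in either table, matched by that keyword. Which libraries entered each selection is not stated, so their overlap was not treated as independent evidence and was not tested.

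Wheat is hexaploid, and most genes have a copy on each of the A, B and D subgenomes. The listed genes numbered 264 on A, 278 on B and 311 on D, and 53.8%, 50.7% and 48.6% of them lay on the positive side. No difference between these shares was detected (permutation test, p = 0.461, adjusted p = 0.461 over 2 tests). Over the 21 chromosomes the split of direction varied more, from 15 of 44 positive on 3D to 20 of 27 on 6D, but the permutation p of 0.0495 became 0.0990 after adjustment. Group 5 chromosomes carried 189 listed genes, 22.2% of those placed, with 107 of them negative.

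Neighbouring genes were listed together at 4 places on group 5 chromosomes, each with at least 5 genes on one side within 10 consecutive gene numbers, and all of these genes were negative. The runs were noticed in the data and not looked for beforehand. They held 7 genes on 5A, 7 on 5B and 5 and 6 on 5D, and their median log2 fold changes were -1.91, -1.74, -4.22 and -1.67. All but 1 of them lacked a description.

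**Figure D3:**
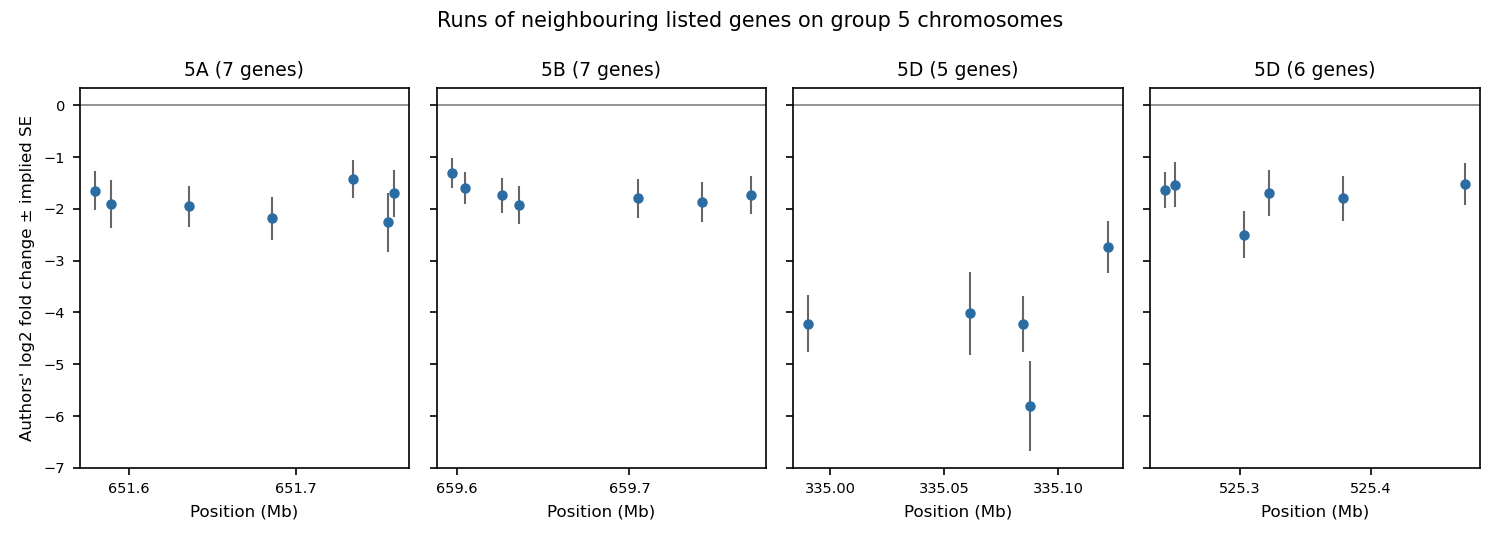
Authors' log2 fold change (vertical axis, orientation not stated) with its implied standard error (bars) against the position of each gene's midpoint in Mb (horizontal axis) for the 4 runs of neighbouring listed genes on chromosomes 5A, 5B and 5D. All points lie below 0, and the run of 5 genes on 5D lies lowest.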

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

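The tests with other described genes as background, one vote per description, an FDR under 0.01 for the lists and the subgenomes, one probe per overlapping group and the shrunk fold were chosen after the data were seen. At an FDR under 0.01 the counts of genes became 169 positive and 192 negative, so the larger count moved from the positive to the negative side. Neither split was tested against an even one. With a minimum absolute log2 fold change of 1 they were 440 and 408, and with one probe per overlapping group 432 and 420. Photosynthesis stayed past the threshold in all 4 list alternatives, with 97.7% to 100% positive. With one vote per description, where 10 descriptions were left, it passed only narrowly (adjusted exact p = 0.0421), and nitrite reductase was among those votes. Chromatin and cell cycle, at 100% positive, passed in 3, narrowly at an FDR under 0.01 (5 members, 3 of them histone-fold genes, adjusted exact p = 0.0436), and not with one vote per description, where only 8 descriptions were left. Against other described genes, 3 further lists passed with unchanged shares. These were kinases at 11.1%, carbohydrate and energy metabolism at 33.3% and protein turnover at 0% positive. That background held the photosynthesis list, with 59 of 60 positive, and the chromatin list, with all 23 positive. These passes therefore rest partly on those lists, and the background was not tried without them. With one vote per description, kinases and carbohydrate and energy metabolism did not pass (adjusted exact p = 0.0611 for both), and protein turnover could not be tested. No other list changed its call where it could be tested, but 7 of the 11 lists had too few members for a test in at least 1 alternative. The subgenome p stayed between 0.449 and 0.478, and the 18 shared genes were the same count by probe, gene or position. Among the 53 named genes, the shrunk fold kept the sign of every one, and 20 had an FDR of 0.01 or more. Normalization, filters on low values, pseudocounts, leaving out a replicate, medians, non-overlapping ranges and splits of the samples were not run, because these tables hold no values per library. The filter to the upper part of mean expression and the alternative tools and scalings planned for counts were not run for the same reason. No paired analysis was possible because the tables carry no replicate columns. Depth is unknown, so what it limits is unknown too.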

Other observations

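All tests in this part were chosen after the values they use had been seen, and so were the genes named here. Glutamyl-tRNA reductase, the committing enzyme of chlorophyll synthesis, was listed on 1A, 1B and 1D with log2 fold changes of 1.69 (SE 0.41), 2.82 (SE 0.37) and 2.07 (SE 0.41). Chloroplast signal recognition particle 43, which delivers antenna proteins to the thylakoid, was listed on 5A, 4B and 4D at 1.84, 2.17 and 2.14. The magnesium-protoporphyrin cyclase genes on 3A and 3D were at 1.34 and 1.28. DNA topoisomerase 2 (TraesCS1D02G260500) and condensin complex subunit 2 (TraesCS6B02G341400), which act on chromosomes but were not in the chromatin list, were at 1.72 (SE 0.42) and 1.75 (SE 0.43). The topoisomerase overlaps an opposite-strand gene listed at 1.67, so its fold is not known to be a separate measurement. On the negative side were glutamate decarboxylase, which makes gamma-aminobutyrate, at -2.09 (TraesCS4A02G075600), -1.60 (TraesCS4B02G231400) and -2.53 (TraesCS4D02G232700), and NAC transcription factors 6A, 6B and 6D at -1.16, -1.18 and -1.13.

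Genes with one description tended to lie on one side. Of 41 descriptions carried by 2 or more genes, 36 were one-sided, 24 positive and 12 negative, against a median of 19 and a maximum of 28 in 10000 shuffles of direction among described genes (permutation p = 0.0001, the smallest they can give). The 8 descriptions with exactly 1 gene on each of A, B and D were all one-sided, 5 positive and 3 negative. This argues against chance direction. Shared regulation and reads shared between near-identical copies both stay open, since how multiply mapping reads were counted is not given in the sources used here.

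Photosynthesis genes were positive in 59 of 60 cases. If all chlorophyll a-b binding copies only shared a common pool of reads evenly, their folds would be equal. Over all 37 copies the folds differed (Cochran's Q = 158, chi-square p = 3.18e-17). They also differed over the 31 with an SE under 0.6 (Q = 118, 30 degrees of freedom, chi-square p = 1.90e-12). That restriction was added afterwards because selection inflates imprecise folds. The test covers only a pool common to all copies, so sharing of reads within smaller sets of copies stays open. Described genes outside the list were more often positive than genes without a description of their own, 60.5% against 44.2% (Fisher's exact p = 0.000201). They included the 23 chromatin genes, all positive, and positive genes of chlorophyll synthesis that the keywords missed. A leaning of described genes may be part of the pattern, but whether it extends beyond such families was not tested. The list also lay above the other described genes (exact p = 6.06e-10 before adjustment). That is the comparison already given in the Results with an adjusted exact p of 6.66e-09, and not a further test. Unequal light exposure or greening of the groups is a candidate explanation, since light induces many of these genes and the seeds germinated in darkness. With 0 listed genes in the light signalling list it stays open, as does an effect of the ultrasound, which is untested here.

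Listed genes without description formed runs on group 5 chromosomes. Within 10 consecutive gene numbers, 7 genes on 5A (651578711 to 651759447), 7 on 5B (659596531 to 659770854) and 6 on 5D (525242551 to 525472578) were listed, all negative, with log2 fold changes from -2.50 to -1.31 and 1 description among the 20, a C2H2 zinc finger protein. In 10000 random placements of the listed genes along the gene numbers of each chromosome, no window held more than 5. For the runs of 6 and 7 genes this argues against chance placement (permutation p = 0.0001, the smallest they can give). The run of 5 genes described below is no larger than random placement reached, so the test does not set it apart from chance. No difference between the 20 folds was detected (Cochran's Q = 9.45, 19 degrees of freedom, chi-square p = 0.965). The test assumes independent errors, which genes measured in the same libraries need not have. Reads shared between near-identical copies cannot be told apart from genes regulated together, because both can give equal folds. A separate run of 5 genes on 5D (334990247 to 335122088), from TraesCS5D02G227000 to TraesCS5D02G227700, had log2 fold changes between -5.80 and -2.74, and no difference between them was detected after adjustment over the 4 runs (Cochran's Q = 10.7, 4 degrees of freedom, chi-square p = 0.0297, adjusted p = 0.119) or over the 3 with an SE under 0.6 (Q = 5.39, chi-square p = 0.0676).

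Overlapping probes were looked at as well. In 9 places 2 listed probes overlapped on opposite strands, and in all 9 both lay on the same side. An example was the aldolase TraesCS5D02G122700 at 1.80 and its opposite-strand neighbour TraesCS5D02G122600 at 1.80. The protocol text describes no strand marking, so the 2 probes of a place are not known to be separate measurements. Their shared side was therefore not taken as evidence of a shared direction. With one probe per overlapping group, 432 genes were positive and 420 negative, against 441 and 420 with all probes. Across the 861 genes, absolute fold and implied SE had a Spearman correlation of 0.886, and a p-value threshold admits imprecise genes only with large folds. Genes are not independent replicates.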
